A study of Homo sapiens with 6 samples.

How the data were processed

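The series holds 6 samples of the human lung adenocarcinoma line A549, grown with 10% serum. Per the labels' protocols, cells received 2 µM HCI-2509 or DMSO on the day after seeding and were harvested after 48 h, and biotin-labelled cDNA was made from 100 ng of total RNA. The groups DMSO and HCI-2509 were taken from the labels, with 3 samples each.

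The values used were the signals in the deposited value table, which holds linear intensities for 53617 probe sets on each of 6 arrays. Per the submitters' processing notes the authors used the Transcriptome Analysis Console, and its version is not given. How probe signals were summarised and normalized is not given in the sources used here. The values range over many orders of magnitude and include signals near 0, so they were taken as linear intensity and not as log2 values. The design chosen before the data were examined expected log2 values, with log2 to be taken first if the table was linear, and this was done with no offset. Column medians differed by 0.263 on the log2 scale, more than the tolerance of 0.1 set beforehand, so quantile normalization was applied between arrays. No background measure was used here. Signals below 1 numbered 1153, 599 and 1127 on the DMSO arrays and 730, 702 and 864 on the HCI-2509 arrays. 2113 rows were identical to another row, and all were kept.

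Probe sets were named through the platform annotation, updated through gene identifiers in a RefSeq table of assembly GRCh38.p14, which was used for names only. 16098 probe sets had 1 symbol, none had several, and the others are unnamed here. Each of the 14884 genes was represented by its probe set with the highest mean over the 6 arrays, a choice that concerned 779 genes with more than 1 probe set. Changes were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, no trend, not robust) with group as the only term, two-sided, HCI-2509 minus DMSO. P-values were adjusted by Benjamini-Hochberg over 53617 probe sets and called at 0.05, with a second threshold of at least 2-fold. Standard errors (SE) are limma's moderated values, and mean ± SD values are over the 3 arrays of a group.

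Gene lists were fixed before the data were examined. They numbered 31, with 917 symbols, of which 574 were measured. The 30 lists with at least 5 measured members were tested with camera (preset correlation 0.01) and Benjamini-Hochberg adjustment over these lists, and again with an estimated correlation. Fry, also planned, tested the same lists for a shift in 1 direction without setting members against other genes. Members were also adjusted over the list alone. List medians were set against 10000 random lists of the same size matched on mean signal. Named genes followed a rule fixed beforehand. It took the 12 largest increases and the 12 largest decreases among called genes whose arrays were separated by group, leaving out uncharacterised loci and non-coding RNA, and 1 decrease qualified. From each list it took the 3 members with the largest absolute change among called ones, or the member with the largest absolute change if none was called, and KDM1A was always given. Other genes were named after their values were seen. Among these are BNIP3L, VEGFA, SESN1, GDF15, DDIT3, MCM10, GINS2, CCNB1, AURKA, CHEK1, CHEK2, NOP2, NOLC1, MYC, GSR, PGD, CCN2, AXL, VIM, INSIG1, APAF1, IFIT3 and GAPDH, and the genes outside the lists in the closing section.

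The procedure was tested on simulated data of the same size, with log2 changes of 1 and of 2 each added to 100 probe sets with a mean log2 signal of at least 5. The main test recovered 16% of log2 changes of 1 and 71% of changes of 2, with 4 unchanged probe sets called. On the brighter 28867 probe sets it recovered 57% and 86%, with 9 unchanged ones called, and with trend and robust variance 40% and 81%, with 7. In the simulated lists the shifted list was called and 0 of 26 unshifted lists were. The simulated noise was independent between genes, so false list calls that come from correlated genes could not appear. Alternatives fixed beforehand were median centring, a minimum mean log2 signal of 5, the brighter 26809 probe sets by rank, named probe sets only, trend with robust variance, array weights, the replicate number as a block, the estimated correlation, the mean over all probe sets of a gene, and leaving out each array. Added after seeing the data were an offset of 16, a floor of 16, no normalization, and the offset together with trend and robust variance or with the block. Figures were drawn with matplotlib.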

Results

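Expression arrays were run on A549 cells, a line from a human lung adenocarcinoma, after 48 h with 2 µM HCI-2509 or with the solvent DMSO. HCI-2509 is known as an inhibitor of LSD1 (KDM1A), a demethylase that removes methyl groups from histone H3. Each group held 3 samples, and each sample gave signals for 53617 probe sets, of which 16098 carried the name of 1 gene and stood for 14884 genes. Median signals were 32.93, 36.73 and 32.61 on the DMSO arrays and 39.12, 37.63 and 37.25 on the HCI-2509 arrays. Signals below 16 made up 26.3%, 19% and 26.4% of the DMSO arrays and 17.8%, 18.7% and 19.8% of the HCI-2509 arrays. Over the 28867 probe sets with a mean log2 signal of at least 5, arrays of the same group correlated at 0.965 to 0.978 and arrays of different groups at 0.945 to 0.961, across probe sets. The labels do not say that the samples came from separate cultures, so limma p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. Camera p-values set the genes of a list against the other genes, so their size is no measure of precision across samples.

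The comparison asked which transcripts differ after 48 h with the inhibitor. IGFBP1 and IGFBP3, which encode binding proteins for insulin-like growth factors, rose 8.18-fold and 6.39-fold. NDRG1, a gene known to be induced by low oxygen, rose 7.89-fold, from a log2 signal of 4.64 ± 0.07 to 7.62 ± 0.12 (SD, 3 arrays per group). The related hormone genes STC1 and STC2, which encode stanniocalcins, rose 5.72-fold and 5.62-fold. VAV3 was the 1 named gene called lower in the main limma test, from 6.89 ± 0.12 to 5.16 ± 0.07, a log2 fold change of -1.73. When only the 28867 brighter probe sets were tested, 315 genes were called lower.

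The remaining genes among the 12 largest increases were ANKRD45 at 9.19-fold, SLAMF7 at 4.92-fold, CREG2 at 4.23-fold, CP at 4.22-fold, ANKRD1 at 4.19-fold, PLIN2 at 3.59-fold and TP53INP1 at 3.42-fold. CP encodes the copper-carrying ferroxidase ceruloplasmin, PLIN2 a coat protein of lipid droplets, and TP53INP1 a nuclear protein induced by p53. The limma adjusted p of these 13 genes lay between 0.00610 for NDRG1 and 0.0482 for CREG2. For each of them all HCI-2509 arrays lay on one side of all DMSO arrays, which was a condition of their selection. Of all probe sets, 24% were separated in this way. ANKRD45 and IGFBP1 were dim in DMSO, at log2 signals of 3.27 ± 0.29 and 4.05 ± 0.46, so their folds depend on how low signals are treated. With 16 added to every signal their log2 fold changes were 2.02 and 2.20 in place of 3.20 and 3.03. Other genes moved less: NDRG1 had 2.38 in place of 2.98, and SLAMF7 1.87 in place of 2.30. CREG2 had 1.58 in place of 2.08, ANKRD1 1.68 in place of 2.07, and VAV3 -1.38 in place of -1.73.

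**Figure D1:**
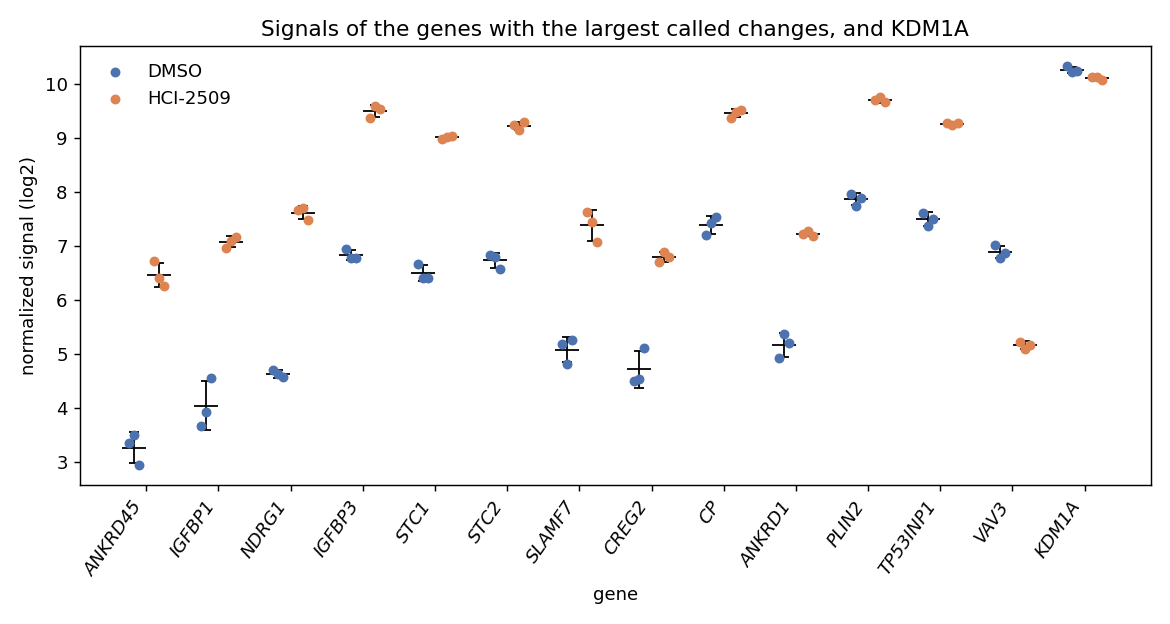
Quantile-normalized log2 signals (vertical axis) of the 13 genes with the largest called changes and of KDM1A (horizontal axis), with 1 point per array, blue for DMSO and orange for HCI-2509; black lines are the group mean and whiskers 1 SD over 3 arrays. The groups do not overlap for any gene shown, which for the 13 genes was a condition of their selection. KDM1A differs by a log2 fold change of -0.14, which did not pass the limma test.

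At a limma adjusted p under 0.05, 91 probe sets differed, 75 higher and 16 lower with HCI-2509, or 82.4% higher. Each of the 91 changed at least 2-fold. Of these probe sets, 34 stood for a named gene, 33 higher and 1 lower, and 57 were unnamed here. 2 of the 34 symbols, LOC100287834 and MIR651, belong to an uncharacterised locus and a microRNA, and were named after their values were seen; their DMSO signals lay near 0, so no fold is given. The number of calls and their balance differed between settings. Centring arrays on their medians gave 31 calls, 22 higher and 9 lower, or 71% higher, and 11 genes. Restricting the test to the 28867 brighter probe sets gave 1475 calls, 741 higher and 734 lower, or 50.2% higher, and 640 genes. Letting the variance follow the mean signal, with a robust fit, gave 2203 calls, 1052 higher and 1151 lower, or 47.8% higher, and 985 genes. 10 of the 34 genes were called in the first of these fits, 30 in the second and 32 in the last. Without any 1 array limma called 1 to 9 genes. Of the 34, between 0 (without DMSO replicate 2) and 7 (without DMSO replicate 3) were among them. In these 6 fits 50% to 72.4% of called probe sets were higher. All 34 kept their direction there, but this was fixed in advance, because the arrays of each gene were separated by group.

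KDM1A, which encodes the known target of the inhibitor, had log2 signals of 10.27 ± 0.06 in DMSO and 10.12 ± 0.03 with HCI-2509. The log2 fold change was -0.14 (SE 0.10), with a limma adjusted p of 0.526, and was -0.35 when arrays were centred on their medians. Of 24 measured members of LSD1 complexes, none passed the limma test over all probe sets. Adjusted over the list alone, CHD4, a chromatin remodeller of the NuRD complex, fell by 0.67 on the log2 scale. The list as a whole had a median log2 fold change of -0.13 and a camera adjusted p of 0.145, and camera called it lower when arrays were centred on their medians (median -0.32, adjusted p = 0.0162) and when they were not normalized (adjusted p = 0.0241).

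Genes known as targets of the hypoxia-inducible factors rose as a group. Of 24 measured members, 5 rose over all probe sets and 18 rose adjusted over the list alone, and none fell. The median log2 fold change was 0.71 (camera adjusted p = 2.741e-16). NDRG1, STC1 and BNIP3 had log2 fold changes of 2.98, 2.52 and 1.56, and BNIP3 encodes a mitochondrial protein that takes part in mitophagy. PGK1, a glycolytic enzyme, and BNIP3L, a relative of BNIP3, were the other called members, at 1.23 and 1.05. VEGFA, which encodes an angiogenic growth factor, and KDM3A, a histone H3 demethylase, rose by 0.94 and 0.93 adjusted over the list alone. This was the 1 list still called by camera with an estimated correlation between genes (adjusted p = 0.0203). Fry gave it an adjusted p of 1.478e-06. Other lists also passed fry, such as replication (adjusted p = 0.00348), mitosis (0.00247) and p53 targets (0.00283). So did lists that camera did not call, such as fatty acid synthesis (0.00506) and the control genes (0.0178). Passing fry therefore does not set a list apart from other genes.

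Measured targets of p53 were also higher. The list held 35 symbols, and CDKN1A and MDM2 were among those without a named probe set here. Of 19 measured members, TP53INP1 and SPATA18 rose over all probe sets, at log2 fold changes of 1.77 and 1.45, and 12 rose adjusted over the list alone, with none lower. Among these 12 were SESN1 at 1.09, PMAIP1 at 1.02 and GDF15 at 0.96, which encode a stress-responsive sestrin, the death-promoting protein NOXA and a secreted stress factor. BAX and BBC3, at -0.01 and 0.12, did not pass. The list median was 0.50 (camera adjusted p = 2.113e-08, and adjusted p = 0.209 with an estimated correlation), and 0.26 when arrays were centred on their medians. Targets of ATF4 in the integrated stress response split. STC2, VLDLR and ATF3 rose over all probe sets, at 2.49, 1.44 and 1.42 (ATF3 0.90 with 16 added to every signal), and 7 of 22 members rose adjusted over the list alone, DDIT3 among them at 0.87. The list median was 0.11 (camera adjusted p = 0.0102, and adjusted p = 0.265 with an estimated correlation), and 8 members had values below 0. The median was -0.02 when arrays were centred on their medians and 0.19 among the 26809 brightest probe sets. In the main test it lay at percentile 93.51 of matched random lists, inside the central 95%.

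Genes of DNA replication and of cell division were lower, though none of them passed the limma test over all probe sets. Adjusted over the list alone, 15 of 27 replication genes fell and none rose. They included MCM6 and MCM10, at log2 fold changes of -1.15 and -1.11, and GINS2 at -1.02, which act in or with the replicative helicase. The list median was -0.46 (camera adjusted p = 8.368e-09, and adjusted p = 0.209 with an estimated correlation). Of 47 genes of G2/M and mitosis, 22 fell adjusted over the list alone, with CDC20 at -0.81, CCNB1 at -0.72 and AURKA at -0.71, known regulators of mitosis. Their median was -0.34 (camera adjusted p = 1.601e-13, and adjusted p = 0.0940 with an estimated correlation). Of 19 genes of homologous recombination and Fanconi repair, 12 fell adjusted over the list alone, led by TIPIN at -0.85, with the checkpoint kinase genes CHEK2 at -0.81 and CHEK1 at -0.71. Their median was -0.34 (camera adjusted p = 2.789e-07, and adjusted p = 0.0940 with an estimated correlation). The medians of the replication, mitosis and repair lists were -0.69, -0.54 and -0.56 when arrays were centred on their medians.

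**Figure D2:**
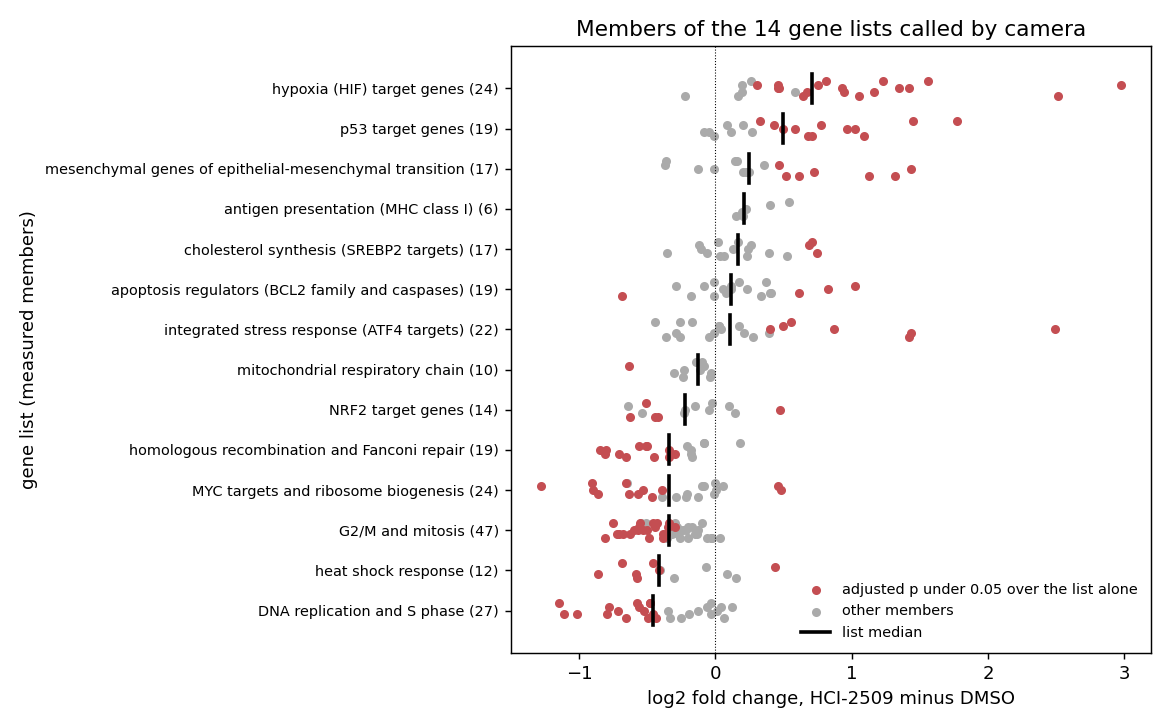
Log2 fold changes, HCI-2509 minus DMSO (horizontal axis), of every measured member of the 14 gene lists called by camera (vertical axis, number of members in brackets); each point is a gene, red where its limma adjusted p over the list alone is under 0.05, and black bars are list medians. Medians run from -0.46 for DNA replication to 0.71 for hypoxia targets, and members of several lists lie on both sides of 0; the median of the integrated stress response list turns to -0.02 when arrays are centred on their medians.

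Ribosome biogenesis genes and MYC targets were lower, with a list median of -0.34 (camera adjusted p = 0.000108, and adjusted p = 0.308 with an estimated correlation), and -0.54 when arrays were centred on their medians. None of the 24 members passed over all probe sets. Adjusted over the list alone, 10 fell and 2 rose. NOP16, NOP2 and NOLC1, which encode nucleolar proteins, had log2 fold changes of -1.28, -0.90 and -0.90, and MYC itself had -0.39 with a limma adjusted p of 0.311. Heat shock genes had a median of -0.41 (camera adjusted p = 0.0122, and adjusted p = 0.265 with an estimated correlation). Adjusted over that list alone 6 of 12 fell and 1 rose, with the co-chaperone gene STIP1 at -0.87. HSPA1A and HSPA1B are near-identical copies whose probes could be shared, so their values are uncertain. NRF2 targets had a median of -0.23 (camera adjusted p = 0.0295, and adjusted p = 0.209 with an estimated correlation), and -0.40 when arrays were centred on their medians. Adjusted over the list alone 4 of 14 fell, GSR at -0.62 and PGD at -0.51 among them, and 1 rose, and SRXN1, at -0.64 and at -0.34 without HCI-2509 replicate 3, did not pass. The NRF2 call ended without DMSO replicate 2 (adjusted p = 0.0693), without HCI-2509 replicate 2 (adjusted p = 0.0551) and among the 26809 brightest probe sets (adjusted p = 0.0529).

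Mesenchymal genes of epithelial-mesenchymal transition were higher, with a median of 0.24 (camera adjusted p = 0.000104, and adjusted p = 0.209 with an estimated correlation), and 0.46 without normalization. LOXL2, a lysyl oxidase relative, rose over all probe sets, at a log2 fold change of 1.44. Of 17 members, 7 rose adjusted over the list alone, including the matrix-associated growth regulator gene CCN2 at 1.32, the receptor kinase gene AXL at 1.13 and VIM at 0.52 (0.34 when arrays were centred on their medians). Of 30 epithelial junction and keratin genes, none passed over all probe sets, and adjusted over the list alone 2 fell and 2 rose. EPCAM had -1.10, and -0.57 with 16 added to every signal, and did not pass. That list's median was -0.03, against a camera direction upwards (adjusted p = 0.903), and was 0.16 without normalization, 0.22 among the 28867 brighter probe sets and 0.06 without DMSO replicate 3, so no direction is given for it.

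Smaller shifts were called for 4 further lists. The list named for MHC class I antigen presentation had 6 measured members, B2M, TAPBP, ERAP1, ERAP2, CD274 and IRF1. No HLA gene, TAP1 or TAP2 was among them, and CD274 and IRF1 are not presentation genes themselves. The median was 0.21 (camera adjusted p = 0.0155), with no single member past a test. CD274 was highest at 0.54 (0.35 with 16 added to every signal). Cholesterol synthesis genes had a median of 0.17 (camera adjusted p = 0.0285), and 3 of 17 rose adjusted over the list alone, EBP at 0.75 and INSIG1 at 0.68 among them. Apoptosis regulators had a median of 0.12 (camera adjusted p = 0.0430). Adjusted over that list alone 3 of 19 rose and 1 fell. PMAIP1 had 1.02 and APAF1 0.83, while BCL2L11 was lowest at -0.69. Genes of the respiratory chain had a median of -0.13 (camera adjusted p = 0.0252), and 1 of 10, CYC1, fell by 0.64 on the log2 scale adjusted over the list alone. With an estimated correlation the adjusted p was 0.209 for the antigen presentation, cholesterol and apoptosis lists and 0.308 for the respiratory chain list. Their medians lay at percentiles 93.72, 97.48, 92.37 and 13.62 of matched random lists, in that order. These lie inside the central 95%, so such medians did not stand out from lists of like signal. Of the alternative settings, camera called antigen presentation in 15 of 18, cholesterol in 14 of 20, apoptosis in 10 of 20 and the respiratory chain in 17 of 20. Leaving out 1 array ended the cholesterol call (adjusted p = 0.0715 without DMSO replicate 1 and 0.0551 without HCI-2509 replicate 2), the respiratory chain call (0.0585 without DMSO replicate 1 and 0.0626 without HCI-2509 replicate 1) and the apoptosis call (0.0996 and 0.0568 without DMSO replicates 2 and 3, and 0.0975 and 0.0600 without HCI-2509 replicates 1 and 3). The cholesterol median was 0.26 without HCI-2509 replicate 1, and the apoptosis median was 0.21 without DMSO replicate 1, 0.19 without HCI-2509 replicate 2 and 0.26 without normalization. When arrays were centred on their medians, the antigen presentation, cholesterol and respiratory chain medians were 0.10, 0.05 and -0.35.

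Among lists not called, CD68 rose over all probe sets, at a log2 fold change of 1.16, while the 10 measured leukocyte markers had a median of 0.16 (camera adjusted p = 0.108); camera called this list higher when arrays were centred on their medians (adjusted p = 0.0320), when they were not normalized (adjusted p = 0.0442) and without DMSO replicate 1 (adjusted p = 0.0412), with medians of 0.34 in the second of these and 0.30 in the last. The 11 measured fibroblast and endothelial markers had a median of 0.06 (camera adjusted p = 0.903), which was -0.10 and -0.03 without HCI-2509 replicates 3 and 1 and 0.13 without DMSO replicate 2, and LUM had 0.52, and 0.12 without DMSO replicate 3. Among 7 measured control genes often used as references, PGK1 rose over all probe sets, and adjusted over the list alone GAPDH rose by 0.52 and IPO8 fell by 0.40 on the log2 scale (0.29 and -0.64 when arrays were centred on their medians). Their median was 0.20 (camera adjusted p = 0.150) and turned to -0.02 when arrays were centred on their medians, and was 0.09 without DMSO replicate 2. CDKN2A and MTAP, at the chromosome 9 locus known to be deleted in this line, had log2 fold changes of -0.29 and -0.40 and adjusted p of 0.471 and 0.372, and were -0.18 without HCI-2509 replicate 2 and -0.24 without HCI-2509 replicate 3. Their log2 signals were 4.11 ± 0.22 and 6.34 ± 0.15 in DMSO and 3.82 ± 0.20 and 5.95 ± 0.29 with HCI-2509, and with no background measure used here these levels do not show whether a transcript was present. With 2 measured members this locus was not tested as a list.

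The other lists were not called by camera in the main test, and single members that passed did so adjusted over the list alone. SAMD9L and IFIT3 rose by 0.99 and 0.99 on the log2 scale among 30 type I interferon response genes (median 0.15, adjusted p = 0.102), a list called in 1 of 20 alternative settings, without HCI-2509 replicate 3 (adjusted p = 0.0392), while without HCI-2509 replicate 1 the median was 0.05 (adjusted p = 0.295), and 0.06 when arrays were centred on their medians. CXCL8, which encodes a neutrophil-attracting chemokine, rose by 1.39, and 2 others of 22 inflammatory genes rose by less, in a list whose median of -0.04 opposed a mean of 0.07 and an upward test (adjusted p = 0.772). GABARAPL1 rose by 0.82, and 1 other of 28 autophagy and lysosome genes rose by less (median 0.12, adjusted p = 0.0872; the median was -0.03 when arrays were centred on their medians, and 0.08 and 0.06 without DMSO replicates 2 and 3). Among 32 histone methyltransferases and demethylases 3 rose, KDM3A the most, and 2 fell (median -0.04, adjusted p = 0.931), with a median of 0.01 among the 28867 brighter probe sets. ELOVL6 had a value of -0.63 and was the 1 of 15 fatty acid synthesis genes that fell (median -0.09, adjusted p = 0.125). That median was -0.17 and -0.13 without DMSO replicates 2 and 3, -0.17 and -0.15 without HCI-2509 replicates 1 and 2, and -0.24 when arrays were centred on their medians. STEAP1 had -1.25, or -0.92 with 16 added to every signal, and fell. Of 10 iron genes 1 other rose, and the list had a median of 0.02, a mean of -0.08 and a downward test (adjusted p = 0.903). MT2A had 1.27, and 1 of 10 metallothionein and zinc genes rose and 1 fell, with a median of -0.01, a mean of 0.01 and a downward test (adjusted p = 0.903); metallothionein copies are alike and their probes could be shared, so these values are uncertain.

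Of the lists not yet described, 4 had no member that passed adjusted over the list alone. The 16 endoplasmic reticulum chaperone genes had a median of 0.01, a mean of -0.04 and an upward test (adjusted p = 0.947), with SDF2L1 at -0.93, and -0.61 without HCI-2509 replicate 3. The 18 alveolar and lung lineage genes had a median of -0.0046, a mean of 0.03 and an upward test (adjusted p = 0.931), with LAMP3 at 0.72, and 0.39 without DMSO replicate 1. The 20 Notch pathway genes had a median of 0.13 (adjusted p = 0.465), with DLL1 at 0.62, and 0.34 without DMSO replicate 3. The Notch median was 0.06 and 0.07 without DMSO replicates 1 and 2 and 0.07 and 0.04 without HCI-2509 replicates 1 and 3. The 21 neuronal genes known to be repressed through REST, a partner of LSD1 complexes, had a median of -0.01, a mean of -0.03 and an upward test (adjusted p = 0.969), with STMN2 at -0.59, and -0.27 without DMSO replicate 3 and -0.25 with 16 added to every signal. The medians of the inflammatory, iron, metallothionein, chaperone, lung lineage and neuronal lists changed sign when arrays were centred on their medians or not normalized, and each also without at least 1 single array, so no direction is given for them.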

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

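The number of calls differed between settings and depended on single arrays. All 34 called genes kept their direction in every alternative that tested them. Their arrays were separated by group, so leaving out an array, a filter or another variance model could not turn a sign. Median centring, no normalization, the offset and the mean over probe sets could have done so. The settings with an offset, a floor or no normalization, alone or combined, were chosen after seeing the data. Planned quantile normalization became the main setting, so it has no separate value. Against 91 probe sets, 91 at 2-fold and 34 genes, median centring gave 31, 31 and 11, a mean log2 signal of at least 5 gave 1475, 317 and 640, the top 26809 probe sets by signal gave 1717, 319 and 743, and trend with robust variance gave 2203, 425 and 985. An offset of 16 gave 897, 209 and 368, a floor of 16 gave 756, 269 and 321, and the offset with trend and robust variance gave 2399, 244 and 1045. Array weights gave 124, 117 and 46. Testing named probe sets only gave 493 probe sets and 468 genes, and the mean over all probe sets of a gene gave 541 genes. The filters test fewer probe sets, and the offset and floor damp low signals by construction. The weight given to the variance shared over probe sets (limma's prior degrees of freedom) was 1.52 in the main fit. It was 2.63 with a mean log2 signal of at least 5, 3.72 with the offset and 4.64 with trend and robust variance. What changed the counts was not tested for any setting. No normalization gave 87 probe sets and 34 genes, 28 of them among the 34 of the main test, but moved the median of all probe sets by 0.13 on the log2 scale. Leaving out any 1 array lowered the counts, to 8 to 29 probe sets, 8 to 29 at 2-fold and 1 to 9 genes. Probe sets and genes were 29 and 9, 8 and 1, and 29 and 8 without DMSO replicates 1, 2 and 3, and 12 and 4, 13 and 3, and 12 and 2 without HCI-2509 replicates 1, 2 and 3; these fits have fewer samples. With the replicate number as a block limma called 0 probe sets, 0 at 2-fold and 0 genes, with 6669 at an unadjusted p under 0.05 against 8455 in the fit without the block, and 67 probe sets with the block and an offset of 16. The numbers were not treated as pairing the samples, since deviations of arrays with the same number correlated at -6.8e-05, 0.03 and -0.04 and 1 of 6 arrays correlated best with its own number. With an estimated correlation 1 list was called; the other settings called 11 to 14, of which 10 to 14 were among the 14. The median of the integrated stress response list was -0.01968 with median centring; the cause was not tested. Over single genes, 184 comparisons with an alternative lost a call, 374 gained one and 1155 kept their side of the threshold with the same sign. Over lists 35 lost a call, 6 gained one and 553 kept their side of the threshold. In 44 of the 553 the median of a list called in neither setting changed sign, and in 24 the camera direction of such a list changed. 1 further list comparison, that of the integrated stress response list, was reversed. Some calls rest on low signals: 18 of the 91 probe sets had a deposited signal below 1 on at least 1 array, 71.4% of the 91 (exact 95% interval 61% to 80.4%) had a mean of at least 5 against 53.8% of all, and no background measure was used here.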

Other observations

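The snaR genes were chosen as a pattern, and their test with an offset of 16, after their values were seen. They took the place of a pattern of dim signals, tested through the 71.4% share given above, so that 3 patterns are weighed.

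Outside the fixed lists, genes named here were chosen after their values were seen, from those called among the 28867 brighter probe sets; apart from JUN, TMEM45A, ALOX5AP and IRS2 they were not called over all probe sets. JUN, a subunit of the AP-1 transcription factor, rose by 1.64 on the log2 scale (limma adjusted p = 0.0342), TMEM45A by 1.62 (0.0192), ALOX5AP, which activates leukotriene synthesis, by 1.65 (0.0434), and IRS2, an adaptor of the insulin receptor, by 1.29 (0.0449). SGK1, a kinase induced by serum and glucocorticoids, and CCNG2, a cyclin known to rise in arrested cells, had 1.45 and 1.35, with adjusted p of 0.00734 and 0.00768 among the brighter probe sets and 0.0503 and 0.0521 over all. Lower values were found for GRB14, an adaptor that binds the insulin receptor, at -1.23 (0.00774 and 0.0521), for EHF, an epithelial transcription factor of the ETS family, at -1.07 (0.00734 and 0.0503), for IQGAP2, a scaffold protein, at -1.04 (0.00734 and 0.0503), and for the secreted epithelial protein gene AGR2 at -1.10 (0.0124 and 0.0706). In each of these pairs the first value is over the brighter probe sets and the second over all.

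The hypoxia target list rose although nothing in the labels speaks of low oxygen. An array bias that depends on signal would leave its median among those of lists of like signal, but the median lay at percentile 100 of 10000 matched random lists. Near-zero signals did not carry it, since the median was 0.6691 with an offset of 16. Nor did 1 array, as the highest camera adjusted p over the 6 fits without an array was 1.439e-13. The treatment itself stays open as the biological explanation; how it would raise these transcripts was not tested, and oxygen, cell density and HIF protein were not analysed here.

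The DNA replication list fell, at percentile 0 of its matched random lists, which argues against a bias that depends on signal. Without any 1 array the highest camera adjusted p was 7.306e-07. The call was lost with an estimated correlation between genes, which was 0.222 for this list (camera adjusted p = 0.209). Calls were also lost for lists with an estimate below 0, such as antigen presentation at -0.124 and cholesterol at -0.014. The loss therefore does not show by itself that the members are correlated. Nor were they shown to be independent evidence. Not all members fell: PCNA, TYMS, RRM2 and CCNE2 had log2 fold changes of -0.03, -0.06, 0.01 and 0.06. No biological explanation was tested, and no cell cycle measure was analysed here.

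Part of the snaR family of small RNAs, which RNA polymerase III transcribes, had lower signals, and the family was not tested as a set. Of 8 measured members, SNAR-D, SNAR-B1, SNAR-C1 and SNAR-H were called among the brighter probe sets, at log2 fold changes of -2.35, -1.33, -1.14 and -0.90, and none over all probe sets; of the others SNAR-G1 and SNAR-I had 0.64 and 0.17 and SNAR-G2 and SNAR-F -0.87 and -0.25. Near-identical copies can share probes, so their values are uncertain and not independent. POLR3G, which encodes a subunit of RNA polymerase III, had -0.99 (limma adjusted p = 0.0123 among the brighter probe sets and 0.0705 over all), the lowest of 5 measured subunit genes, whose median was -0.17. POLR3B had -0.53 (0.0349 and 0.135), POLR3C -0.17 and POLR3E -0.16, and POLR3GL, a paralog of POLR3G, had 0.25. The median over all 8 snaR genes was -0.883, and -0.6358 with an offset of 16, so near-zero signals did not account for most of it. Whether RNA polymerase III transcripts fell in general stays open. Of 24 others listed before their values were looked at, 6 were measured, 5 of them with a mean log2 signal below 5. The other, RMRP, was called among the brighter probe sets at -0.81 (limma adjusted p = 0.0406 there and 0.150 over all). The median of the 6 was -0.618 and passed the bound of -0.5 set beforehand. Its 95% bootstrap interval ran from -0.895 to 0.0627, and the demand that this interval also lie below -0.25 was added after the value was seen. With an offset of 16, RMRP, VTRNA1-3 and RPPH1 had -0.60, -0.56 and -0.55. VTRNA1-2, VTRNA2-1 and VTRNA1-1 had -0.27, -0.13 and 0.05 with that offset.

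The 10 splits of the 6 arrays are too few for a share under 0.05, and in each case 1 split, the real one, reached its count. The real split gave 91 probe sets, against at most 9 in the others, 91 against at most 9 at 2-fold, 34 genes against at most 1, and 14 lists against at most 4.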
